A study of Homo sapiens with 2 samples.

How the data were processed

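RNA of H1299 cells without and with 5 mM metformin was sequenced as 1 library each; the duration of treatment is not given in the sources used here. Per the labels' protocols, libraries were made with the TruSeq Stranded mRNA LT kit and sequenced on a NovaSeq 6000. The labels name more than 1 aligner: reads were mapped to hg19 with Bowtie2 per the labels' protocols, while Trimmomatic 0.38, HISAT2 and the builds hg19 and GRCh37 are named per the submitters' processing notes. The program that made the abundances is not given in the sources used here, and the columns have the layout of a StringTie gene abundance table. Whether counting used the strand is likewise not given.

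Per the file headers, each library has a deposited table with 1 row per gene (28157 rows in control, 28160 in metformin, 27685 gene IDs in each) with position, coverage, FPKM and TPM. TPM was computed by the authors and summed to 1000000 per library. FPKM was likewise deposited, and coverage was deposited as mean read depth over a gene's exons. The TPM column was used for all main values, FPKM for an alternative, and coverage for the depth and for another alternative. A TPM is relative to all other transcripts, so the rise of abundant transcripts lowers the rest.

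Depth was recovered from the ratio of coverage to FPKM, whose largest value gave 5.80 Gb of aligned bases in control and 6.40 Gb in metformin. A read pair was taken as 202 bases (2 reads of 101), the most common base total of short genes with few reads (35 of 1181 in control and 48 of 1132 in metformin). That gave 28.7 M and 31.7 M read pairs. Pairs per gene were estimated from FPKM and the canonical transcript length of GENCODE 44 on GRCh37, and these summed to 107% of the total in each library. From them came the exact (Clopper-Pearson) 95% interval of each fold, which covers counting error only, not the variation between cultures; PCR duplicates can make it too narrow.

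The tables give NCBI gene IDs without symbols. Symbols were taken from a RefSeq gene table (assembly GRCh38, used for names only), which matched 27559 IDs and left 126 unmatched, with 0.437% of TPM in control and 0.505% in metformin. Of 23587 symbols also in GENCODE, 99.5% overlapped their GENCODE position. Rows of the 353 IDs listed more than once were summed, and coordinates are those of the deposited tables, on hg19. Genes that overlap on the same strand, read-through models and copies at several loci can exchange reads and were marked in the computation, though not at every mention in the text. Of the 191 named genes, 34 overlap a gene on the other strand, so their reads cannot be told apart if the strand was not used.

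The difference of log2(TPM + 1), metformin minus control, was computed per gene with a pseudocount of 1, so folds on that scale understate differences of low genes; folds in the text are plain TPM ratios. A gene was measured at a TPM of 1 or more in at least 1 library and counted as higher or lower at a difference of 1 or more in size (2-fold). All counts of genes or list members past 2-fold use this difference, not the plain TPM ratio. With 1 library per group no test was run. For 40 gene lists fixed before the data were examined, as were the measure, the thresholds and most of the alternatives, the median over measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart outside the central 95%. Lists with fewer than 5 measured members, 5 of the 40, got values only. The trend of the difference over GC content and transcript length was fitted across genes and removed in an alternative; 93.7% of measured genes had both. Intervals given with list medians are 95% order-statistic intervals over the members.

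Genes were named by a fixed rule. It took the 15 genes with the largest and the 15 with the smallest difference among genes with 5 TPM or more in a library at a single named locus, leaving out ribosomal protein, histone, small RNA and LOC or LINC genes. It added up to 2 genes at each end of every list with at least 5 measured members, 24 genes named in advance, and the 10 genes of highest mean TPM. Any other gene is said to be named after its values were seen. Some genes the rule took are not reported here.

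The steps were tested on simulated data for the same comparison over 12953 genes, all with a known transcript length. Single changed genes were planted only among those with 5 TPM or more in control, so their result does not cover lower genes. All genes planted at 3-fold in either direction passed the 2-fold rule (100% of 50 each way), and 0% of those at 1.5-fold did. Of 12724 unchanged genes, 4 passed it by counting noise. Counts were drawn with counting noise alone. That number therefore does not cover genes without a known length, reads exchanged between genes or differences between cultures. A planted list shifted by 0.3 lay at percentile 100, and 6.5% of 200 unchanged lists fell outside the central 95%. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives covered the pseudocount, FPKM or coverage in place of TPM, the scaling, the minimum TPM, the fold threshold, duplicate rows, the list statistic, the bins, shared members, the GC and length trend, gene type and genes that can exchange reads.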

Results

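The effect of metformin on the transcriptome of lung cancer cells was examined by RNA sequencing of H1299, a human non-small cell lung cancer line. Metformin is a biguanide used against type 2 diabetes and is known to inhibit complex I of the mitochondrial respiratory chain. The data were 1 library from untreated cells (control) and 1 library from cells given 5 mM metformin. Gene abundances were listed in TPM, a transcript abundance corrected for length and relative to all transcripts of the library. The control library held 5.80 Gb of aligned bases, an estimated 28.7 M read pairs, and the metformin library held 6.40 Gb, an estimated 31.7 M read pairs. A TPM of 1 or more was listed for 13717 genes in control and 13767 in metformin. Over the 14078 genes at that level in at least 1 library, the log2(TPM + 1) values of the libraries were correlated across genes, which are not independent replicates, at a Pearson r of 0.979. There were no replicates, so no difference has a replicate check, no p-value is given, and the 95% intervals on fold values cover the counting of reads only.

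In the metformin library, RHOB, a small GTPase known as an early stress-response gene, was higher by 12.6-fold (95% counting interval 11.6 to 13.6), with a TPM of 23.2 in control and 291 in metformin. RHOB (NCBI gene 388) lies on chromosome 2 at 20646832 to 20649204 of hg19. TP53INP2, which takes part in autophagosome formation, was higher by 6.44-fold (5.80 to 7.18), and KLF2, a zinc finger transcription factor, by 5.13-fold (4.61 to 5.72). TRAF1, an adaptor of TNF receptor signalling and a known NF-kB target, was higher by 4.95-fold (4.61 to 5.32), from 17.0 to 84.2 TPM. GNA12, a G protein alpha subunit, was higher by 4.18-fold, and DEPP1, a known FOXO target, by 4.07-fold. CYB5R3, an NADH-cytochrome b5 reductase, was listed at 57.0 and 207 TPM in control and metformin, 3.63-fold higher in metformin. JUN, a subunit of the AP-1 transcription factor, was higher by 3.82-fold. MSC, SFN and CXCL3 had TPM values of 1.08 or less in control and between 5.32 and 7.05 in metformin, so their ratios rested on few control reads, with an interval of 4.28 to 10.1 for MSC and 3.61 to 15.1 for CXCL3. DEPP1 and MSC overlap another gene on the opposite strand, and whether counting used the strand is not given in the sources used here.

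At the other end, CKAP2L, a mitotic spindle protein, had 0.255 of its control TPM in metformin (95% counting interval 0.239 to 0.273), with a TPM of 72.0 in control and 18.4 in metformin. LSM4, a subunit of the Lsm ring that binds U6 small nuclear RNA, stood at 0.310 of its control TPM, the mediator subunit MED29 at 0.362 and the mitochondrial ribosomal protein MRPS27 at 0.363. STARD4, a cholesterol transfer protein, was listed at 29.9 TPM in control and 10.2 in metformin, a ratio of 0.341. SMIM30, which encodes a small membrane protein, stood at 0.295 of control, GUCD1, which overlaps SNRPD3 on the other strand, at 0.303, the zinc finger gene ZMAT1 at 0.156 and VSTM1 at 0.275. TAF9, a subunit of the general transcription factor TFIID, was listed at 297 and 99.5 TPM, a ratio of 0.335, though its exons overlap those of AK6 on the same strand. The pseudogene HERC2P4, a partial copy of HERC2, was listed at 7.70 TPM in control and at 0 in metformin, but it overlaps another pseudogene on the same strand with which it can exchange reads.

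Across the transcriptome, 213 of the 14078 measured genes were higher by 2-fold or more in metformin on the log2(TPM + 1) scale and 175 were lower, which was 1.51% and 1.24%. Among the 12230 protein-coding genes, 146 were higher and 104 lower, while microRNA and small nucleolar RNA genes made up 41 of the higher and 42 of the lower genes. On the log2(TPM + 1) scale, 87.6% of the measured genes lay within 1.5-fold of control. The pseudocount shrinks differences of low genes, so for plain TPM ratios the share is at most this. Counts of list members past 2-fold given below are on the log2(TPM + 1) scale too. The split of higher against lower genes depended on the scaling of the libraries: the median difference over genes at 10 TPM or more in both libraries was -0.09, and after centring on it 270 genes were higher and 114 lower, so the share of higher genes moved from 54.9% to 70.3%. With trimmed mean scaling the counts were 262 and 130, a share of 66.8%. The difference also went with the GC content of the transcript (Spearman correlation 0.35 over 13185 genes), with a median of -0.27 in the tenth of genes with the lowest GC content and 0.09 in that with the highest. Of the called genes, 61 of the higher and 63 of the lower overlapped, or had a copy of, another gene with which reads can be exchanged.

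**Figure D1:**
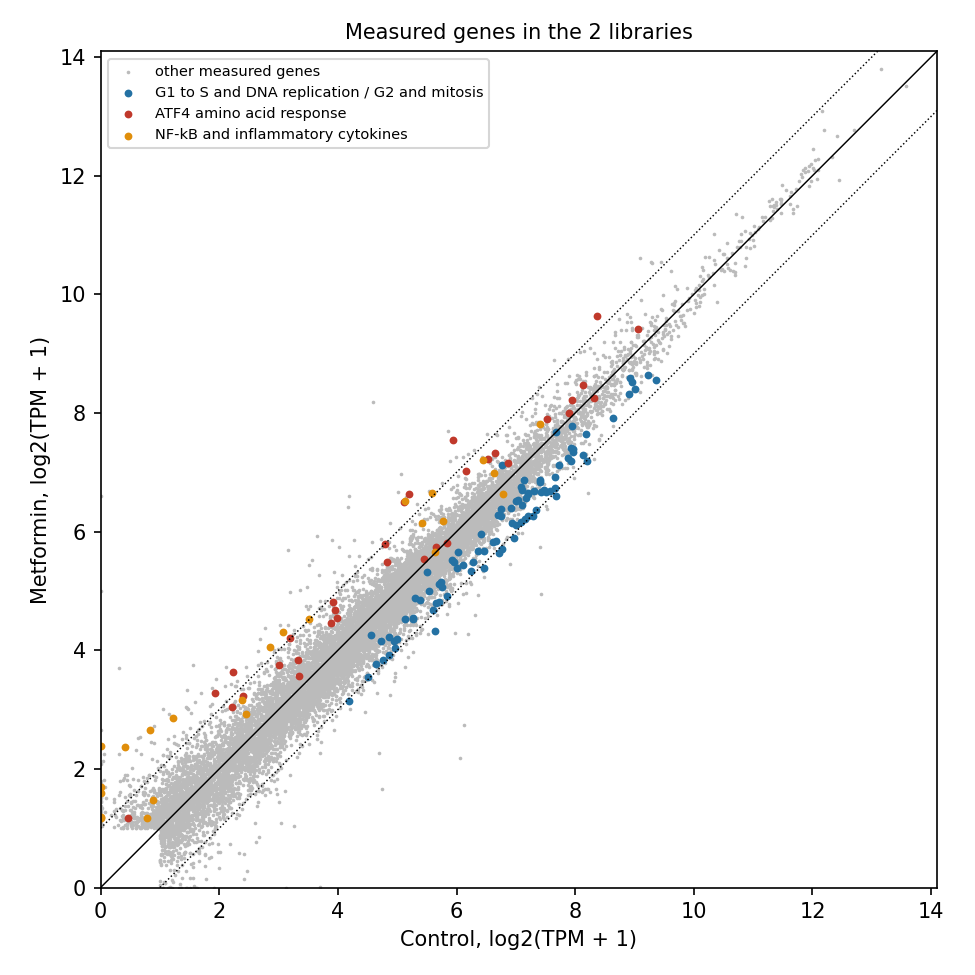
Expression of each of the 14078 measured genes as log2(TPM + 1) in the control library (horizontal axis) and in the metformin library (vertical axis); the solid line marks equal values and the dotted lines a difference of 1. Of the 91 members of the G1 to S and mitosis lists, 1 lies above the line, and members of the ATF4 and NF-kB lists lie mostly above it.

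Several of the most extreme values came from read-through annotations, in which 1 transcript model spans 2 neighbouring genes. RFLNA, also called FAM101A, was listed at 0 TPM in control and 95.5 in metformin, while the model ZNF664-RFLNA was listed at 68.5 and 5.69, and the sum over ZNF664, RFLNA and the joint model was 213 and 218 TPM. MICOS10-NBL1 was listed at 25.0 and 3.83 TPM with a ratio of 0.978 for the sum of its locus. ISY1-RAB43 was listed at 1.94 and 12.4 TPM with a ratio of 1.08 for the sum. The CCPG1 locus, which encodes an endoplasmic reticulum autophagy receptor, had a summed ratio of 0.472, with CCPG1 itself at 28.3 and 8.49 TPM, the joint model DNAAF4-CCPG1 at 0 and 5.28, and DNAAF4 at 5.62 and 2.26. SERF2-C15ORF63 was listed at 0 and 31.1 TPM, and the sum with SERF2 and HYPK had a ratio of 0.966.

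Genes of the amino acid response driven by the transcription factor ATF4 had the second highest median of the fixed lists with 5 or more measured members. Of the 32 measured members of that list, 30 lay above 0, with a median log2 difference of 0.68. On the log2(TPM + 1) scale, 8 were higher by 2-fold or more. ASNS, asparagine synthetase, was higher by 2.40-fold (95% counting interval 2.34 to 2.45), from 330 to 791 TPM. TRIB3, a pseudokinase induced by ATF4 and CHOP, was higher by 2.77-fold, SESN2, a leucine sensor that restrains mTORC1, by 2.04-fold, and DDIT3, which encodes CHOP, by 1.84-fold. DDIT4, an inhibitor of mTORC1 also called REDD1, was listed at 60.8 TPM in control and 186 in metformin, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, at 33.8 and 89.9. ATF4 itself was higher by 1.29-fold, and GDF15, a secreted stress cytokine, was listed at 4.29 and 8.39 TPM. SLC38A2, a glutamine and alanine transporter, and ATF5 stood at 0.961 and 0.977 of control, but the log2 difference of SLC38A2 turned from -0.06 to 0.13 without the GC and length trend. The median lay at percentile 100 of 10000 random lists of the same size and expression, whose central 95% ran from -0.21 to 0.05, and was 0.60 after removal of the GC and length trend.

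In the list of serine and one-carbon synthesis, PHGDH, the entry enzyme of serine synthesis, was higher by 2.19-fold (2.08 to 2.31). PSAT1, the aminotransferase after it, was higher by 1.67-fold, and PSPH, the phosphatase that ends the pathway and was named after its values were seen, was listed at 46.2 and 50.3 TPM, whereas TYMS, which encodes thymidylate synthase, stood at 0.650 of control. With 8 members above 0 and 7 below, the list had no common direction: its median was 0.12 (percentile 98.5) and its mean -0.021. Of the 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 lay above 0 with a median of 0.20 (percentile 99.9). GARS1 and WARS1, for glycine and tryptophan, were higher by 1.62-fold and 1.60-fold, and FARSB, for phenylalanine, stood at 0.798 of control.

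Targets of the transcription factor NF-kB and inflammatory cytokines had the highest median of these lists, 1.03. Of 24 measured members, 23 lay above 0 and 13 were higher by 2-fold or more on the log2(TPM + 1) scale. CXCL1 and CXCL3, neutrophil-attracting chemokines, were listed at 1.33 and 0.783 TPM in control and at 6.24 and 5.32 in metformin. BIRC3, an inhibitor of apoptosis and NF-kB target, was higher by 2.10-fold (2.03 to 2.18), from 47.1 to 99.1 TPM. The cytokine genes CCL20, CXCL8, CSF2, CXCL10 and CCL5, named after their values were seen, were listed at 0 in control and between 1.26 and 4.24 TPM in metformin. NFKB1, the p50 precursor, was listed at 48.5 and 49.4 TPM, and SOD2, mitochondrial superoxide dismutase, stood at 0.901 of control. In control 15 members reached 1 TPM, and the other 9 counted as measured only through the metformin library, which makes their differences positive. Among the 15, 14 lay above 0 with a median of 0.76, and over all 30 fixed members with no minimum the median was 0.75. The median of all measured members lay at percentile 100 of the random lists and was 0.999 after removal of the GC and length trend. It was 0.512 with a pseudocount of 5, since many members were at low levels. The lowest ATF4 median under any alternative was 0.515, so the order of these lists turned at that pseudocount.

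Immediate early genes of MAPK signalling had no common direction, with 10 of 26 members above 0 and a median of -0.19 (percentile 6.33). JUN and JUND, AP-1 subunits, were higher by 3.82-fold and 2.20-fold, while ETV4 and EGR1, transcription factors induced through ERK, stood at 0.451 and 0.582 of control. ETV4 overlaps DHX8 on the other strand. The interferon response had a median of 0.05 (percentile 97.4), between ISG20, an exonuclease, at 2.24-fold and IFITM2, a membrane protein that restricts viral entry, at 0.699 of control.

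Genes of DNA replication and mitosis lay below their control values in nearly all members. All 45 measured members of the G1 to S list lay below 0, with a median log2 difference of -0.64, and 45 of the 46 members of the G2 and mitosis list, with a median of -0.74. MKI67, the proliferation marker Ki-67, was listed at 161 TPM in control and 81.2 in metformin, a ratio of 0.506 (95% counting interval 0.495 to 0.516). ASPM, a spindle pole protein, stood at 0.394 of control, NDC80, a kinetochore subunit, at 0.468, FBXO5, an inhibitor of the anaphase-promoting complex, at 0.473, and E2F2, a transcription factor of S phase entry, at 0.457. CDC25B, a phosphatase that activates CDK1, was the member above 0, at 1.28-fold, and CDC25C stood at 0.871. CDK4 stood at 0.890 of control and CCND1, which encodes cyclin D1, was listed at 204 TPM in each library, a ratio of 0.998 (0.972 to 1.02). In the G1 to S list 3 members and in the G2 and mitosis list 6 were lower by 2-fold or more, and none was higher. Both medians lay at percentile 0 of the random lists and were -0.68 and -0.66 after removal of the GC and length trend.

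Among inhibitors of the cell cycle, 14 of 19 lay above 0, with a median of 0.18 (percentile 99.9). CDKN2D, an inhibitor of CDK4 and CDK6, was higher by 2.58-fold (2.17 to 3.08), GADD45A, a growth arrest gene, by 1.91-fold and CDKN1A, which encodes p21, by 1.77-fold (1.67 to 1.88), whereas the pocket protein gene RBL1 stood at 0.555 and CDKN2C at 0.692 of control. Replication-dependent histone genes went the other way from the replication list, with 13 of 15 above 0, 4 higher by 2-fold or more and a median of 0.63 (percentile 100). With the 9 members below 1 TPM in both libraries included, the median was 0.30 over 24 members. H2BC5 was higher by 4.07-fold (3.22 to 5.27), and H2AC18, which has a near-identical copy and is therefore uncertain, was listed at 15.8 and 37.7 TPM. H2AC11 and H2AC20 stood at 0.964 and 0.739 of control, each with an interval that included 1. Most mRNAs of these genes lack a poly(A) tail, so a library made from selected mRNA holds a small part of them.

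Nuclear genes of the respiratory chain, the target of metformin named above, lay close to the bulk of genes. The median was -0.10 for 38 genes listed under complex I (percentile 36.3) and -0.13 for 39 listed under complexes II to V (percentile 9.76). Over all measured genes it was -0.08, and no list member was higher or lower by 2-fold. The complex I list holds NDUFA4, now named COXFA4, a subunit of complex IV, and the other list holds CYCS, the carrier cytochrome c. Both were named after their values were seen. NDUFS4 and NDUFA13 were higher by 1.25-fold each, NDUFA5 stood at 0.671 and NDUFC2 at 0.730 of control. NDUFC2 overlaps the read-through model NDUFC2-KCTD14 on the same strand, with which it can exchange reads. In complexes II and III, SDHA was higher by 1.24-fold and UQCRC2 by 1.12-fold, and SDHD and UQCR10 stood at 0.657 and 0.688. RNR1 and RNR2, the ribosomal RNAs of the mitochondrial genome, were listed at 1294 and 4595 TPM in control and 2072 and 8678 in metformin. RNR1 was named after its values were seen. Of 15 fixed transcripts of the mitochondrial genome only these 2 were matched, so its mRNAs were not measured. Both are ribosomal RNAs in libraries made with an mRNA kit, and their values do not speak for mitochondrial mRNAs. Mitochondrial biogenesis and quality control had a median of -0.19 (percentile 8.0), with TFAM, which packages mitochondrial DNA, at 0.603 and the protease OMA1 at 0.606 of control, and with PINK1, a kinase of mitophagy, and POLG, the mitochondrial DNA polymerase, higher by 1.57-fold and 1.46-fold. PPARGC1A, a coactivator of mitochondrial biogenesis, was listed at 2.64 and 2.81 TPM. The citric acid cycle had a median of -0.09, between IDH2 at 1.34-fold, IDH1 at 1.24-fold and IDH3A at 0.726.

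Glycolysis genes had a median of -0.11 over 25 members, percentile 30.4 of the random lists, with 20 below 0 and none lower or higher by 2-fold. PFKFB4, a regulator of phosphofructokinase, stood at 0.600 and PGK1, phosphoglycerate kinase, at 0.748 of control, while PFKL and PKM, phosphofructokinase and pyruvate kinase, were higher by 1.21-fold and 1.15-fold. HK2, hexokinase 2, was listed at 23.5 and 25.7 TPM. Targets of the hypoxia factor HIF had a median of -0.23 (percentile 4.67), with ERO1A at 0.672, HILPDA at 0.699, P4HA2 at 1.45-fold and BHLHE40 at 1.58-fold. VEGFA, a growth factor for vessels, was higher by 1.12-fold (1.04 to 1.21). In gluconeogenesis and glycogen metabolism the median was -0.10, and besides PCK2 the glycogen phosphorylase PYGB was higher by 1.69-fold, with UGP2 at 0.759 and PPP1R3B at 0.686 of control.

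Fatty acid synthesis had a median of 0.18 over 16 members (percentile 99.8), with 9 above 0 and 7 below. SCD, stearoyl-CoA desaturase, was listed at 1169 and 1587 TPM, 1.36-fold higher, and ACSS2, acetyl-CoA synthetase, was higher by 1.55-fold, while the desaturases FADS1 and FADS2 stood at 0.706 and 0.647 of control. The mean of the members did not stand apart from the random lists. Cholesterol synthesis had a median of -0.09 (percentile 55.5), with LSS and TM7SF2 higher by 1.28-fold and 1.30-fold, CYP51A1 at 0.714 and HMGCS1 at 0.889 of control. TM7SF2 overlaps VPS51 on the same strand. Fatty acid oxidation had a median of -0.02, with ANGPTL4, an inhibitor of lipoprotein lipase, at 0.553, HADH at 0.801, ACADVL at 1.11-fold and ACADS at 1.28-fold.

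Genes of AMPK, the energy-sensing kinase that metformin is known to activate, and of its upstream kinases had a median of -0.08 over 22 members, percentile 54.0 of the random lists. PRKAA1 and PRKAA2, the catalytic subunits of AMPK, stood at 0.786 (0.751 to 0.823) and 0.855 of control, but their log2 differences went from -0.34 and -0.17 to -0.15 and 0.03 without the GC and length trend. STK11, which encodes the upstream kinase LKB1, was listed at 40.3 and 39.6 TPM. NUAK2, an AMPK-related kinase, was higher by 1.95-fold and CAMKK2 by 1.39-fold, with FNIP2 at 0.654 and PPM1E at 0.744. mTORC1 and insulin signalling had a median of -0.06, with 1 of 27 members past 2-fold on the log2(TPM + 1) scale. That member was IGFBP6, an inhibitor of insulin-like growth factor 2, with a plain TPM ratio of 2.73 (1.89 to 3.92). TSC2, a brake on mTORC1, was higher by 1.26-fold. Of the transporters of metformin, SLC47A1 was listed at 4.14 and 4.32 TPM and SLC22A3 at 0 in both libraries. TXNIP, an inhibitor of glucose uptake, was listed at 0.0277 and 0 TPM.

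In the list of cytosolic heat shock genes, 14 of 16 members lay below 0, none of them by 2-fold or more. The median was -0.32 (percentile 0.09), or -0.37 after removal of the GC and length trend. The list also holds the mitochondrial chaperonin genes HSPD1 and HSPE1, at 0.705 and 0.645 of control, both named after their values were seen. HSPH1, a large chaperone of the HSP70 family, stood at 0.615 and CHORDC1, a partner of HSP90, at 0.579 of control, and HSP90AA1, the inducible HSP90, was listed at 5611 and 3910 TPM. The small chaperone HSPB1 was higher by 2.14-fold (2.08 to 2.20), from 701 to 1496 TPM, and DNAJB4 by 1.04-fold. Chaperones of the endoplasmic reticulum had a median of -0.21 (percentile 2.95), with HERPUD1 and XBP1, of the unfolded protein response, higher by 1.71-fold and 1.57-fold and SSR1 and SDF2L1 at 0.640 and 0.673. Targets of NRF2, the regulator of antioxidant genes, lay above 0 in 25 of 31 members, of which 2 were higher by 2-fold or more, with a median of 0.23 (percentile 100). TXNRD1, thioredoxin reductase, was higher by 2.38-fold (2.32 to 2.43) and OSGIN1 by 2.06-fold. TXNRD1 overlaps EID3 on the same strand. GCLC, of glutathione synthesis, stood at 0.894 and NFE2L2, which encodes NRF2, at 0.972 of control. Metal handling genes had a median of 0.05, with TFRC, the transferrin receptor, higher by 1.73-fold, the copper chaperone CCS listed at 26.8 and 39.8 TPM and the zinc transporters SLC39A10 and SLC30A1 at 0.637 and 0.630.

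The 77 ribosomal protein genes had a median of 0.09 (percentile 99.8) with 65 above 0, of which RPL12 was higher by 1.35-fold and RPL34 by 1.25-fold, with RPS27A at 0.807 and RPL13A at 0.773. RPL13A overlaps RPL13AP5 on the same strand. Ribosome biogenesis factors had a median of -0.21 (percentile 1.91) with 27 of 31 below 0, among them NOP58, of the box C/D complex, at 0.602 and UTP20 at 0.687 of control, whereas RRP12 was higher by 1.26-fold. MYC, a transcription factor that drives ribosome production, was higher by 1.24-fold (1.20 to 1.27). After removal of the GC and length trend, the ribosome biogenesis median of -0.19 lay at percentile 5.68. Autophagy and lysosome genes had a median of 0.07 (percentile 99.6), with the autophagy genes WIPI1 and OPTN higher by 1.71-fold and 1.67-fold and ATG12 at 0.776, but the median was -0.0066 (percentile 95.1) without that trend. Apoptosis genes had a median of -0.07, with BIRC3 and BMF, a BH3-only activator of cell death, at 2.10-fold and 2.35-fold and APAF1 at 0.671.

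Of the genes of the epithelial state, 9 of 10 measured members lay above 0, with a median of 0.57 (percentile 100). None was higher by 2-fold or more on the log2(TPM + 1) scale. The other 12 of the 22 fixed members were below 1 TPM in both libraries, among them the keratin KRT19 at 0.167 and 0.148 TPM and the transcription factor GRHL2 at 0, both named after their values were seen, and with them the median was 0.28. KRT8 and KRT18, partner keratins of simple epithelia, were listed at 269 and 553 TPM in control and 521 and 954 in metformin, 1.94-fold and 1.72-fold higher. KRT8 and KRT18 overlap on opposite strands. TJP1, a tight junction protein, was higher by 1.16-fold, and OCLN, occludin, stood at 0.969. Of the mesenchymal and TGF-beta genes, 20 of 25 members lay above 0 and 1 was higher by 2-fold or more, with a median of 0.24 (percentile 100). TGFBI, a matrix protein induced by TGF-beta, was higher by 2.44-fold (2.32 to 2.57) and ID3 by 1.98-fold, VIM, the intermediate filament vimentin, was listed at 4378 and 4962 TPM, and TGFBR2 and CDH2 stood at 0.722 and 0.834. YAP targets had a median of -0.08, between ANKRD1, a cardiac ankyrin repeat protein, at 2.87-fold and NT5E, the ectonucleotidase CD73, at 0.664, with FJX1 at 0.770. Chromatin modifying enzymes had a median of -0.15 over 52 members, with HDAC5 and SIRT7 at 1.64-fold and 1.40-fold and EZH2, the H3K27 methyltransferase, and HELLS at 0.635 and 0.532.

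**Figure D2:**
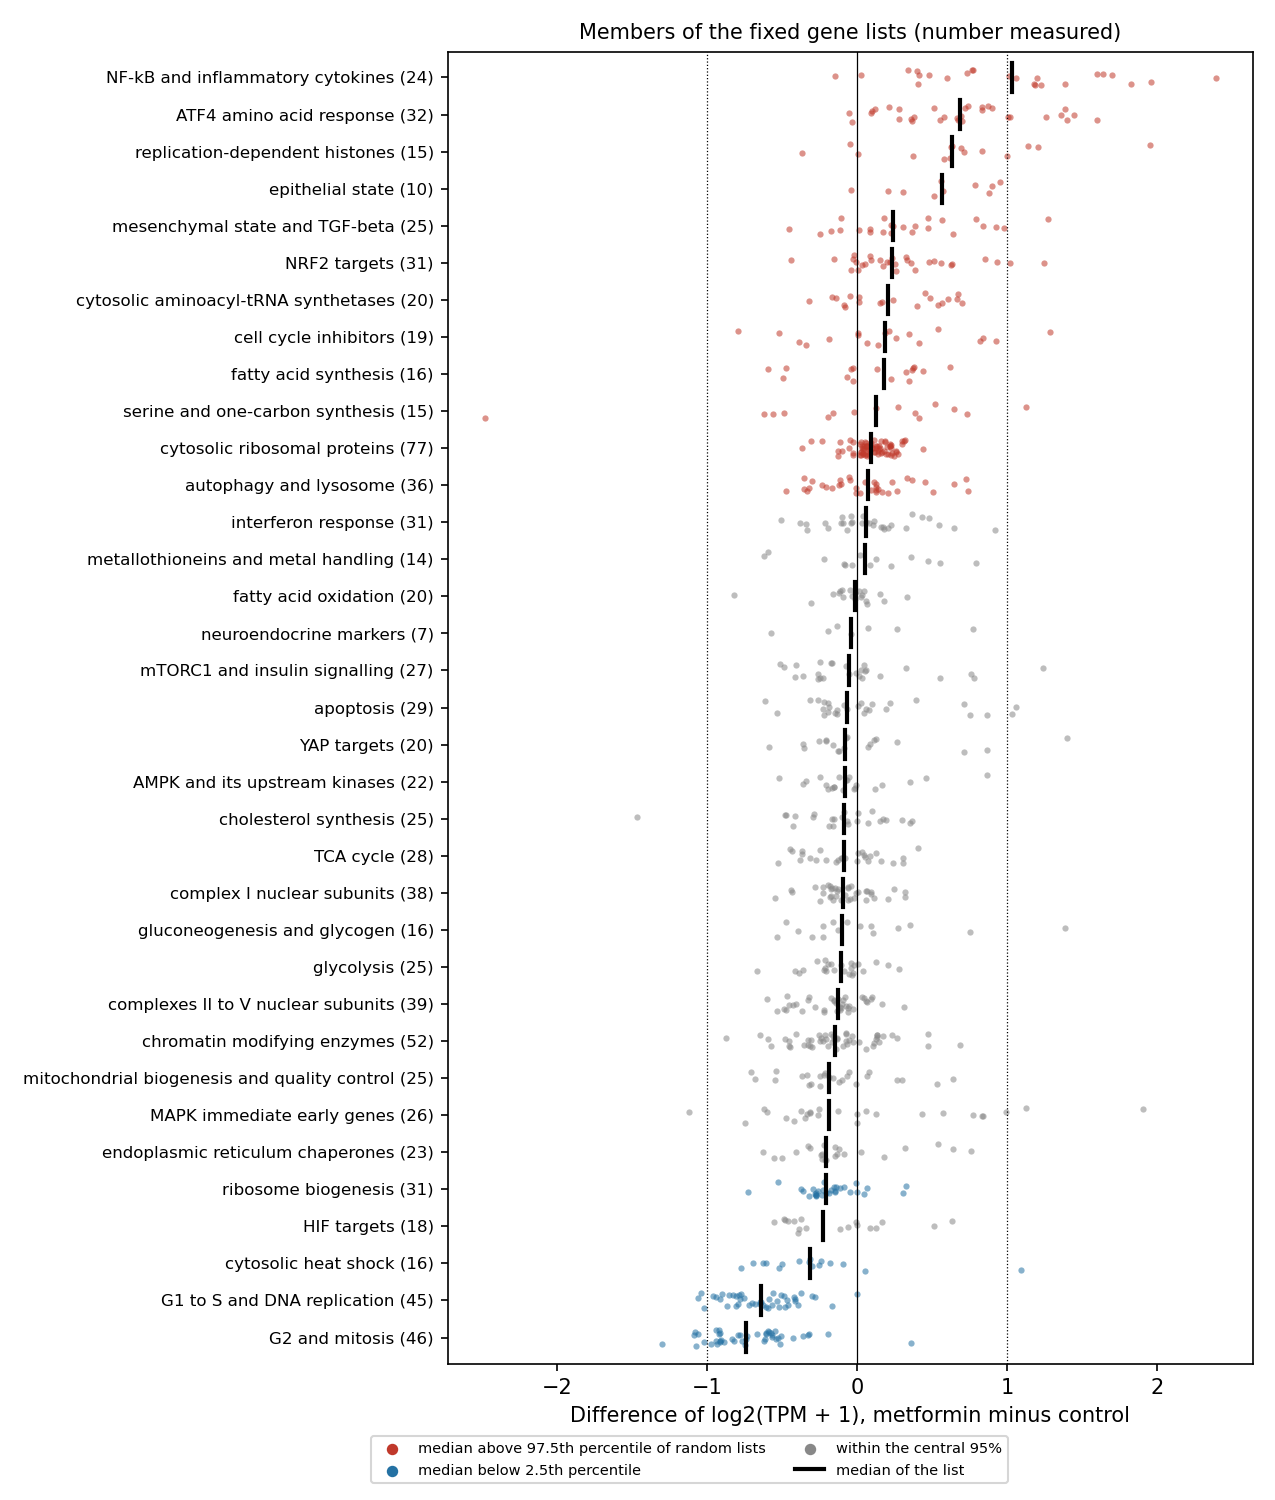
Difference of log2(TPM + 1), metformin minus control (horizontal axis), of each measured member (points) of the 35 fixed gene lists with 5 or more measured members, with the median of each list as a black bar. The 12 lists in red and the 4 in blue have medians above or below the central 95% of matched random lists, from 1.03 for NF-kB and inflammatory cytokines to -0.74 for G2 and mitosis.

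Haematopoietic, endothelial and fibroblast markers were at low levels in both libraries, apart from CD68. Of the haematopoietic markers, 3 reached 1 TPM in control and 2 in metformin. CD68, a lysosomal protein also made by many other cells, was listed at 148 and 115 TPM, and ITGAM at 1.89 and 2.06. Of the endothelial and fibroblast markers, TAGLN was listed at 7.43 and 7.66 TPM and ACTA2 at 6.74 and 7.64. In the lung lineage list, 4 genes were measured: GATA6 was higher by 1.47-fold, FOXA1 and AGER stood at 0.860 and 0.926 of control, and SOX2 was listed at 2.95 and 0.511 TPM. The genes of these 3 lists were named after their values were seen. Neuroendocrine markers had a median of -0.04 over 7 members, with UCHL1, a neuronal deubiquitinase, at 783 and 1340 TPM, CHGB at 1.22-fold, DLL3 at 0.862 and SYP at 0.636.

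**Figure D3:**
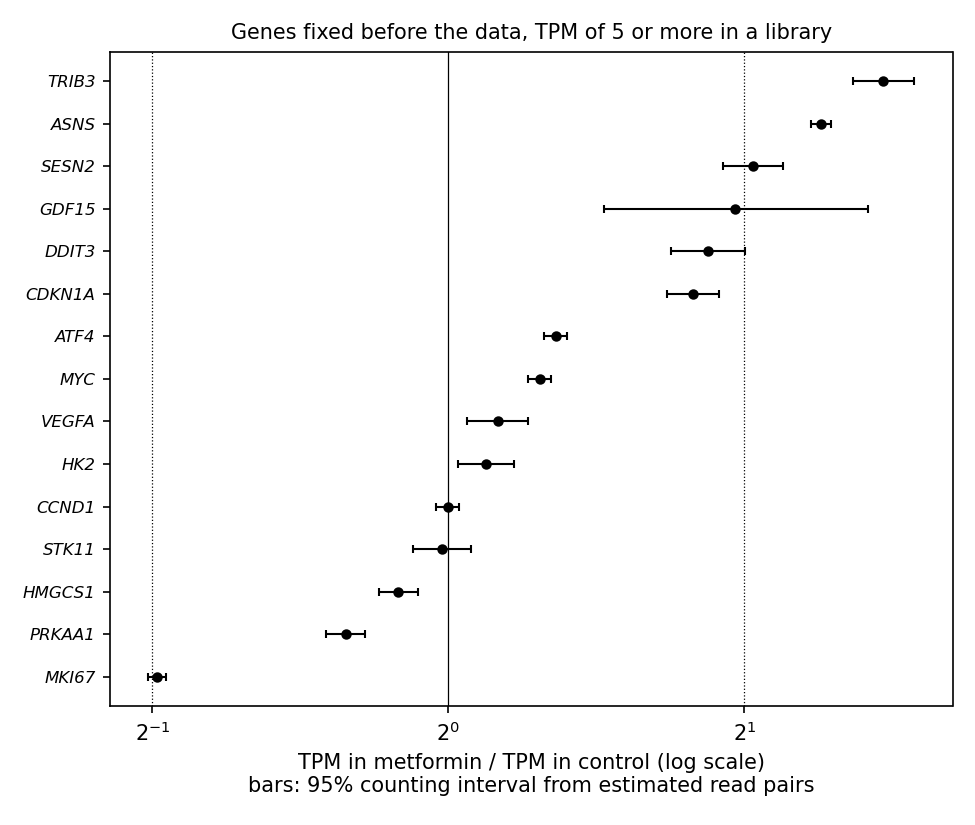
Ratio of TPM in metformin to TPM in control on a log2 axis for 15 of the genes fixed in advance with at least 5 TPM in a library and an interval; bars are 95% counting intervals from estimated read pairs. TRIB3 is the highest at 2.77-fold, and MKI67 the lowest at 0.506.

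Over all 35 lists with at least 5 measured members, 12 medians lay above the central 95% of random lists and 4 below it, where chance gives 1.75 lists outside. Among the lists that did not stand apart, the medians for AMPK, mTORC1 and insulin signalling, cholesterol synthesis, fatty acid oxidation, apoptosis, YAP targets and neuroendocrine markers turned from below to above 0 after centring, to at most 0.07. The percentiles describe these libraries, since genes are not replicates. Among the most abundant genes, GAPDH, the glycolytic enzyme often used as a reference, was listed at 12169 and 11732 TPM, EEF1A1, a translation elongation factor, at 9170 and 14203, and TMSB10, a thymosin that binds actin, at 4708 and 7009. The ribosomal protein genes RPL7, RPS18 and RPL8 were listed at 6685, 5434 and 5172 TPM in control and 7028, 6552 and 5077 in metformin. The 10 most abundant genes took 6.23% of all TPM in control and 7.58% in metformin.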

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

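The alternatives with coverage, without the GC and length trend, with protein-coding genes alone and without genes that can exchange reads were chosen after seeing the data. Of the 16 lists that stood apart, 12 did so under all 15 alternatives, among them ATF4 (medians 0.52 to 0.77), NF-kB (0.51 to 1.12), G1 to S (-0.68 to -0.55) and G2 and mitosis (-0.75 to -0.66). Centring could not change which lists stood apart, since it shifts a list and its random lists alike. FPKM and trimmed mean scaling differ from TPM by 1 constant per library. They could act only through the pseudocount and the minimum. Coverage tracked TPM closely: apart from a shared shift, 36 genes differed by more than 0.5 in log2 difference. The 15 alternatives are therefore not independent checks. Serine and one-carbon synthesis was lost with no minimum, with a minimum of 10 TPM and with the mean, which turned to -0.021. Fatty acid synthesis was lost with the mean. Autophagy and lysosome was lost without the GC and length trend, turning to -0.0066, and ribosome biogenesis with the mean and without that trend. Centring gave 0.16 for autophagy and lysosome, 0.18 for ribosomal proteins and -0.12 for ribosome biogenesis, and trimmed mean scaling 0.16, 0.18 and -0.13, shifts of all genes alike. With no minimum the histone median was 0.30 and the epithelial one 0.28.

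The number of genes past 2-fold depended on how low genes were treated. It was 742 (389 higher, 353 lower) with a pseudocount of 0.1 and 103 (58 and 45) with 5, 180 (113 and 67) with FPKM, 236 (121 and 115) with a minimum of 5 TPM and 172 (91 and 81) with 10 TPM. At 1.5-fold, 1750 genes passed (760 higher, 990 lower) and at 4-fold 24 (14 and 10). Without the GC and length trend 223 passed (132 and 91), among protein-coding genes 250 with 104 lower, after centring 114 were lower, and among genes that cannot exchange reads 112 were lower. Except by construction (fewer genes, a shifted centre or another threshold), the cause was not tested. Of 1710 recomputed values of named genes, 118 moved by more than the half-width of their counting interval, taken as at least 0.1. No called gene changed sign. Centring and trimmed mean scaling apply log2 constants of -0.0883 and -0.0869, smaller in size than 0.1. Neither could therefore count as a move or turn the sign of a called gene. Without the GC and length trend the sign turned for 5 named genes under 2-fold, SLC38A2, NFE2L2, NFKB1, OCLN and PRKAA2. Of the 388 genes past 2-fold, 270 had a counting interval, which lay beyond 1.5-fold for 145 higher and 121 lower genes; no interval was computed for the rest of the 388. No paired analysis was possible because each group has 1 library.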

Other observations

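The families, the gene runs along chromosomes and the tests of low counts, of GC content in the zinc finger cluster and of another difference between the cultures were chosen after the results were seen; the other tests of GC content and that of shared reads were set out before their results. Gene families taken by the start of their symbol showed further groups. The nucleoporins (NUP), which build the nuclear pore, lay below 0 in 21 of 22 members with a median of -0.36, or -0.29 without the GC and length trend. The ALG enzymes, which assemble the sugar chain for protein glycosylation, lay below 0 in 11 of 13 (median -0.35), and the LSM proteins, which bind small nuclear RNAs and mRNA ends, in 12 of 13 (median -0.29). The MCM genes, most of them subunits of the replicative helicase, had a median of -0.63 with 8 of 10 below 0; some of them are also in the replication list. The zinc finger genes (ZNF) lay below 0 in 381 of 461, with a median of -0.24, or -0.22 without the trend. Each of these families lay below the central 95% of matched random lists with and without the trend.

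Other families lay on the higher side. The GOLGA proteins of the Golgi surface lay above 0 in 12 of 15 members (median 0.25), the TNF receptors (TNFRSF) in 11 of 14 (median 0.30), and the CHMP subunits of the ESCRT machinery in 8 of 11 (median 0.12). The myosins (MYO) lay above 0 in 11 of 13 with a median of 0.23, which was 0.12 and within the central 95% without the trend. The VPS genes of endosomal sorting had a median of 0.07, and the SEC genes, many of them of vesicle coats, 0.11. The TMED cargo receptors had a median of -0.33 and the ARL GTPases of -0.26, which were -0.18 and -0.07 and within the central 95% without the trend. Of 140 families of at least 10 measured genes, 14 lay below and 8 above the central 95%, where chance gives 7 in all, and of 138 without the trend 8 lay below and 9 above, where it gives 6.9.

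The lower cell cycle lists held 91 genes with a median of -0.67. A GC and length trend was excluded as the whole cause, since the median without it was -0.67 (95% interval -0.72 to -0.58), where random lists ran from -0.16 to -0.03. A slower cycle under metformin is a hypothesis and a difference in density or handling between the cultures another. With 1 library per group these cannot be told apart, and that holds for the patterns that follow too.

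The ATF4 and NF-kB lists together had a median of 0.74. Without the GC and length trend it was 0.66 (0.50 to 0.87), above random lists, which ended at 0.02. Low counts were not the cause as a whole in either list: members with a mean of 10 TPM or more over both libraries had a median of 0.57 for ATF4 (0.28 to 0.87, 26 genes) and 0.75 for NF-kB (0.34 to 1.20, 12 genes), each above random lists. For the 12 weaker NF-kB members low counts stay open, as 9 of the 24 were measured only through the metformin library. A response to metformin stays an untested hypothesis, and its test would need at least 2 libraries per group.

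Along the chromosomes, the lowest run of 21 neighbouring genes lay in the zinc finger cluster of 19p12, at -0.68, and 0 of 100 shuffles of gene order gave a run as low (lowest -0.53). The 33 measured ZNF genes there, on chromosome 19 at 19778962 to 24312769 of hg19, had a median of -0.67 with 32 below 0, and 473 other ZNF genes a median of -0.23. Of these 473, 383 lay below 0, and their median without the GC and length trend was -0.19. Low GC content (median 36.8% against 43.3% in other ZNF genes) accounts for a part: without the GC and length trend the median was -0.47 (-0.59 to -0.43), and 0 of 100 shuffles of these values gave a run as low, though the lowest, also -0.43, was close to the end of the interval. Reads moved between near-identical members would leave the sum unchanged, but it stood at 0.568 of control (0.553 to 0.583), from 297 to 169 TPM. A shared regulation of the cluster in metformin may remain as a hypothesis, beside a difference between the cultures. Lower values were not particular to the cluster, since most ZNF genes elsewhere also lay below 0, though less far.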
